A study of Arabidopsis thaliana with 24 samples.

How the data were processed

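Gene expression was taken from 24 RNA-seq libraries of Arabidopsis thaliana embryos, 3 for each of 8 groups. The groups are apical cell, basal cell, embryo proper and suspensor, each from a Col mother crossed with a Ler father and from a Ler mother crossed with a Col father. The series text speaks of a 1-cell stage where the sample labels give embryos of 2 cells; apical and basal cell both exist only after the zygote has divided, so the labels are followed here. Per the labels' protocols, cDNA was amplified with a SMART-Seq kit for low input. For 20 libraries the labels name Nextera XT for library preparation, and for 4 they name Nextera XT or NEBNext. Those 4 are basal cell Ler replicates 2 and 3, basal cell Col replicate 3 and suspensor Ler replicate 1, so this difference lies wholly within the basal lineage.

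The deposited FPKM values (fragments per kilobase of transcript and M mapped fragments) were made by the authors, 1 value per locus and library, rounded to 2 decimals. Per the submitters' processing notes TopHat2 2.1.1 and RSEM (no version given) were used on the TAIR10 genome; the notes do not give the role or order of the tools. The files list 32399 loci, of which 31912 are in the TAIR10.1 gene table used here for names and 487 are not. No plastid or mitochondrial loci are listed, so the lists drawn up for those genomes had no members. No coordinates were used. The values are totals per gene, and parental alleles were not analysed here. Summed FPKM ran from 912475 to 1249916 per library. Depth is not stated. It was estimated at about 15.7 to 36.4 M fragments. The estimate uses the most common product of low FPKM values and exon length, less an assumed fragment length. At that depth an FPKM near 1 rests on few fragments for short genes.

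Genes with an FPKM of at least 1 in at least 3 libraries were tested, 18206 in all. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), with 8 group means in 1 fit of all 24 libraries and p-values adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The 10 contrasts were apical against basal cell, embryo proper against suspensor, embryo proper against apical cell, suspensor against basal cell, Col against Ler mother in each cell type and on average over them, and the interaction of lineage and stage. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

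The 15 gene lists were drawn up before the values were seen. They are embryo proper regulators, suspensor and basal lineage regulators, epidermis and cuticle, auxin synthesis, transport and response, cell cycle and DNA replication, photosynthesis, seed storage and maturation, endosperm markers, seed coat markers, genes imprinted in endosperm, DNA methylation and chromatin, gibberellin synthesis, sugar and amino acid transport, stress and wounding, and reference genes. Together they hold 310 distinct genes, 249 of them tested. Lists were tested with camera of limma at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists within a contrast. Members were counted by the call of each gene, adjusted over all genes and over the list alone.

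Genes were named by a rule set beforehand. For the 4 contrasts between cell types it takes the 10 largest changes in each direction among called genes with a mean FPKM of at least 10 in the higher cell type and no overlap between the libraries of the cell types. For the crosses and the interaction it takes 5 in each direction. From each list it takes up to 4 called members with the largest change, or the 2 with the highest mean if none is called, and 17 genes such as WOX2, WOX8 and LEC1 were tabulated whatever their values.

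The model was tested on simulated data with normal noise and a spread for each cell type, smoothed over the mean level. Both crosses of a cell type thus had the same spread, as did genes of the same mean level. With no differences the contrasts gave 0 calls on average, except 0.2 for embryo proper against suspensor, 4.4 for suspensor against basal cell and 201.8 for the crosses in the suspensor, whose replicates vary more than the shared estimate. Of genes changed by 1 or 2 on the log2 scale the fit recovered 35.2 and 92.4% for apical against basal cell, and 13.2 and 50.8% for the crosses in the basal cell. With changed genes present, calls of unchanged genes averaged 4.8 for apical against basal cell and 14.8 for embryo proper against suspensor. For the crosses in apical cell, basal cell, embryo proper and suspensor they averaged 4.2, 7, 0 and 350.

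Alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter at FPKM 5, rescaling to TPM, quantile normalization, median-ratio scaling, library weights, the protocol wording as a covariate, the fit without the 4 libraries, the replicate number as a block, a fit without trend, a 2-fold threshold, each cross alone, and each library left out in turn. A fit of only the libraries compared was added after the data were seen, as were lists of phosphate starvation genes and 5 gene families. The scalings shift the median gene. Its log2 difference for apical against basal cell was 0.03 as deposited and 0.14 on the TPM scale; for embryo proper against apical cell it was -0.07 and, under median-ratio scaling, 0.04, and for suspensor against basal cell -0.15 and -0.04.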

Results

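Total RNA levels were measured in Arabidopsis thaliana embryos grown from reciprocal crosses between the accessions Columbia (Col) and Landsberg erecta (Ler). The apical cell and the basal cell are the daughters of the zygote and were taken from embryos of 2 cells. The embryo proper, which becomes the seedling, and the suspensor, the stalk that joins it to the maternal tissue, were taken from embryos of 32 cells. Each of the 4 cell types came from both directions of the cross. There are 3 libraries in each of the 8 groups, 24 in all. A library held between 12611 and 15366 loci at an FPKM of at least 1. Its depth, estimated from low values and exon lengths, was about 15.7 to 36.4 M fragments. In the suspensor the 10 most abundant loci took 16.1 to 26.3% of the summed FPKM, against 4.32 to 6.73% in the other cell types. The median SD of a gene between replicates, on the log2(FPKM + 1) scale, was 0.224 and 0.265 in the 2 groups of embryo proper and 0.569 and 0.749 in those of suspensor. Values below are mean FPKM ± SD with n = 6 libraries per cell type or n = 3 per cell type and cross, and log2 changes are on the log2(FPKM + 1) scale. That scale understates changes of weakly expressed genes. The labels do not say that replicates came from separate plants, so p-values measure only the spread between these samples.

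The first comparison asked how the 2 daughters of the zygote differ. The apical cell held more RNA of DRN, a transcription factor of the embryo apex, at 54.9 ± 13.1 against 2.54 ± 2.34 in the basal cell (n = 6 each), a log2 difference of 4.26 (SE 0.44, limma adjusted p = 4.26e-07). HAN, a GATA factor, stood at 184 ± 49.6 against 30.7 ± 16.2, and the Argonaute gene AGO5 at 158 ± 32.5 against 14.8 ± 7.56. The basal cell held more of the homeobox gene WOX8, at 239 ± 32.4 against 38.9 ± 21.5 (log2 -2.76, SE 0.26, limma adjusted p = 1.45e-07). Its relative WOX9 was at 342 ± 84.0 against 12.4 ± 8.41 (log2 -4.92, SE 0.36, limma adjusted p = 2.91e-09). PIN7, an auxin efflux carrier, was at 1.03 ± 1.04 in the apical cell and higher in the basal cell (log2 -2.48, limma adjusted p = 0.00019). WRKY2, an activator of WOX8, was at 27.9 ± 5.49 in the basal cell against 6.96 ± 6.22. WOX2, the homeobox gene of the apical lineage, was at 166 ± 76.3 in the apical and 94.4 ± 27.1 in the basal cell and was not called (limma adjusted p = 0.188). Some other settings did call it: a pseudocount of 5, the protocol covariate, the fit without suspensor Ler replicate 1, and the early libraries fitted alone, the last chosen after the data were seen (limma adjusted p = 0.0374, 0.0347, 0.0206 and 0.0429).

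Among the genes with the largest apical excess were MYB96, a regulator of cuticular wax genes, at 127 ± 83.0 against 9.85 ± 10.6, and the GATA factor BME3, at 52.7 ± 13.1 against 3.29 ± 2.87. So was the TRAF-like gene AT2G01790 at 495 ± 92.9 against 37.6 ± 14.6. AT4G01170, of unknown function, was at 19.6 ± 4.22 in the apical cell and listed at 0 in all 6 basal libraries. On the basal side stood the cupin gene AT4G28703 at 208 ± 85.9 against 2.19 ± 4.51, and the calmodulin-like gene CML11 at 190.1 ± 70.5 against 2.42 ± 3.2. NAKR1, a metal-binding protein of the phloem, was at 444 ± 200.3 against 7.81 ± 6.19, and the homeobox gene HB17 at 115 ± 39.9 against 2.04 ± 2.11. The inhibitor-like gene AT5G50070, of the invertase and pectin methylesterase inhibitor family, was at 338 ± 128 in the basal and 5.21 ± 5.43 in the apical cell. The log2 differences of these 5 basal genes ran from -6.70 for AT4G28703 to -5.47 for HB17.

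Of the 15 gene lists, DNA methylation and chromatin genes were the only set that camera called at the preset correlation between the daughter cells. Of 27 tested members 13 were higher in the apical cell and 2 lower (14 and 2 when adjusted over the list alone, camera adjusted p = 0.00109, and adjusted p = 0.0792 with an estimated correlation). The de novo DNA methyltransferase gene DRM1 was at 39.8 ± 10.8 against 2.79 ± 2.44, the CHG methyltransferase gene CMT3 at 155 ± 34.8 against 59.9 ± 7.50, and AGO4 at 155 ± 32.3 against 39.5 ± 11.8. Of 39 cell cycle and DNA replication genes, 9 were higher in the apical cell and 0 lower (10 and 0 when adjusted over the list alone), although camera did not call the list (adjusted p = 0.0687, and adjusted p = 0.581 with an estimated correlation). They included MCM2, a subunit of the replicative helicase, at 83.3 ± 20.4 against 7.15 ± 4.77, and MCM3 at 65.9 ± 30.3 against 17.0 ± 7.99. Of 11 sugar and amino acid transporters 1 was higher and 4 lower (2 and 6 when adjusted over the list alone, camera adjusted p = 0.0687). The sucrose carrier SUC5 stood at 249.6 ± 139 in the basal cell against 19.3 ± 14.1, and the amino acid permease AAP8 at 380.5 ± 101 against 41.0 ± 23.2. The sugar exporter SWEET12 stood instead at 623 ± 234 in the apical cell against 301 ± 91.8. Of 8 tested endosperm markers, among them SUC5, 1 was higher and 2 lower in the apical cell. Camera did not call that list (adjusted p = 0.278), but fry of limma placed it lower (adjusted p = 0.017). Fry called other lists that camera did not. It placed embryo proper regulators, auxin genes and gibberellin synthesis genes higher in the apical cell (fry adjusted p = 0.0327 each). Seed storage and reference genes were placed higher too (fry adjusted p = 0.0347 and 0.0141), and sugar and amino acid transporters lower (fry adjusted p = 2.1e-05). Of 12 tested seed coat markers 1 was higher and 3 lower (camera adjusted p = 0.422). For endosperm and seed coat markers the counts were the same when adjusted over the list alone. Embryo proper regulators (5 higher and 3 lower of 34) and suspensor and basal lineage regulators (5 higher and 4 lower of 17) went both ways.

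In all, limma called 2145 genes higher and 2219 lower in the apical than in the basal cell among 18206 tested. The balance turned with scaling, to 2764 and 1911 on the TPM scale, 2390 and 2248 under quantile normalization and 2247 and 2117 under median-ratio scaling. Within the cross with a Col mother 2532 genes were called and within the cross with a Ler mother 2668. Library weights raised the count to 6715. All 4 libraries whose protocol text allows another library kit belong to the basal lineage, 3 of them to the basal cell. With that wording as a covariate 3168 of the 4364 calls were kept.

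By the 32-celled stage the lineages stood further apart. The little zipper gene ZPR3, which restrains class III homeodomain factors, was at 236 ± 75.8 in the embryo proper and at 0.0267 ± 0.0653 in the suspensor (log2 7.79, SE 0.28, limma adjusted p = 1.28e-15, n = 6 each). The glutaredoxin gene ROXY1 was at 117 ± 40.7 against 1.08 ± 2.64, and HAN at 117 ± 34.6 against 1.12 ± 2.09 (log2 6.15). Among the genes with the largest excess in the suspensor, the cysteine-rich peptide gene LCR48 stood at 21614 ± 11788 against 8.99 ± 6.30 (log2 -11.33, SE 0.68) and the thionin family gene AT5G63085 at 16975 ± 9164 against 11.3 ± 14.3. The S1 self-incompatibility family gene AT1G04645 stood at 19510.1 ± 11675 against 10.6 ± 10 in the embryo proper. The trypsin inhibitor gene TI1 was at 816 ± 516 against 0.140 ± 0.239. Of the lineage regulators, WOX8 was at 373 ± 27.6 in the suspensor against 0.488 ± 0.507, PIN7 at 57.3 ± 20.7 against 3.01 ± 1.78, and WOX2 at 2.77 ± 3.65 against 88.0 ± 12 in the embryo proper.

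**Figure D1:**
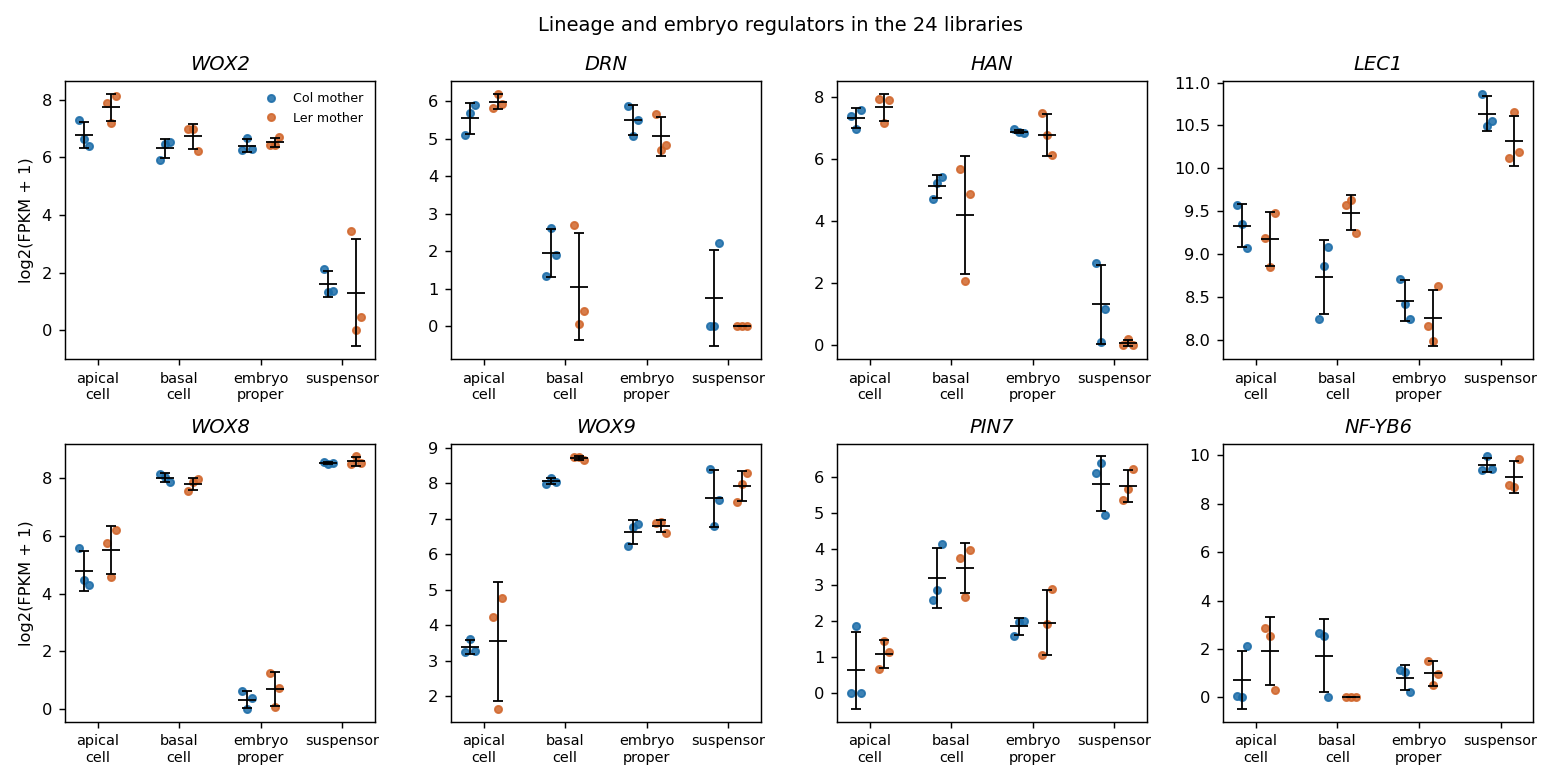
Each point is 1 library, placed by its log2(FPKM + 1), for 8 regulators in the 4 cell types (blue Col mother, orange Ler mother, black bars mean and SD, n = 3). WOX8 is low in the embryo proper (0.488 FPKM on average) and high in basal cell and suspensor, HAN is high in the embryo proper (117 FPKM), and NF-YB6 is high in the suspensor (691 FPKM).

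Cell cycle and DNA replication genes made the most uniform of the 15 lists between the 32-celled lineages, with 37 of 39 higher in the embryo proper and 0 lower (37 and 1 when adjusted over the list alone). Their median log2 difference was 3.18 (camera adjusted p = 1.58e-09, and adjusted p = 0.0823 with an estimated correlation). The mitotic cyclin CYCB1-1 was at 83.3 ± 25.5 against 10.9 ± 18.0, the cytokinesis syntaxin KN at 162 ± 39.0 against 18.9 ± 34.7, and the sliding clamp gene PCNA1 at 311 ± 45.4 against 42.4 ± 26.0. The cyclin-dependent kinase CDKA-1 was not called, at 45.5 ± 4.51 and 74.2 ± 25.2 (limma adjusted p = 0.0591). Embryo proper regulators were higher in the embryo proper, with 27 of 34 higher and 4 lower (the same counts when adjusted over the list alone, median 2.44, camera adjusted p = 8.01e-07, and adjusted p = 0.00452 with an estimated correlation). TMO5, a target of auxin response in provascular cells, was at 48.9 ± 24.4, CUC2, a boundary gene, at 15.5 ± 4.35, and the stem cell gene WUS at 3.84 ± 2.05, and all 3 were listed at 0 in every suspensor library. The 4 members lower in the embryo proper included LEC1, a central regulator of embryo identity, at 332 ± 64.7 against 1450.2 ± 283, and its paralog NF-YB6, at 0.957 ± 0.604 against 691 ± 240.3. The others were the B3 factor FUS3 at 8.37 ± 3.70 against 244 ± 96.3 and AS2, a leaf polarity gene, at 0.130 ± 0.139 against 18.2 ± 9.68.

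Epidermis and cuticle genes were higher in the embryo proper in 9 of 15 cases and lower in 0 (the same when adjusted over the list alone, camera adjusted p = 0.0438, and adjusted p = 0.312 with an estimated correlation). The epidermal gene PDF1 was at 4614 ± 662 against 1156 ± 638, a call lost within the cross with a Ler mother (limma adjusted p = 0.0604). Sugar and amino acid transporters fell in the embryo proper relative to the suspensor, with 9 of 11 lower and 1 higher (the same when adjusted over the list alone, median -2.21, camera adjusted p = 1.41e-04, and adjusted p = 0.00452 with an estimated correlation). SWEET12 stood at 12.1 ± 6.78 against 1030.1 ± 274 in the suspensor, AAP8 at 1.33 ± 0.557 against 276 ± 72.8, and SUC5 at 1.5 ± 0.528 against 161 ± 70.7. Of 16 stress and wounding genes 13 were lower in the embryo proper and 0 higher (13 and 0 when adjusted over the list alone, camera adjusted p = 2.94e-05, and adjusted p = 0.0931 with an estimated correlation). The touch gene TCH4 was at 239 ± 118 against 1017 ± 502, the oxidase gene RBOHD at 0.877 ± 1.67 against 27.3 ± 15.1, and ZAT10 at 2.08 ± 2.69 against 88.7 ± 82.1. Stress genes therefore differed between the same groups as the share of FPKM in the 10 most abundant loci, which averaged 20.7 ± 3.81% in suspensor and 6.39 ± 0.247% in embryo proper libraries.

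The remaining lists were not called by camera between the 32-celled lineages. Auxin genes divided, with 14 of 28 higher in the embryo proper and 6 lower (15 and 8 when adjusted over the list alone, camera adjusted p = 0.451). Those higher included the tryptophan aminotransferase TAA1 at 27.8 ± 5.92 against 0.0467 ± 0.114 and the influx carrier AUX1 at 47.7 ± 11.1 against 0.178 ± 0.427. Those lower included the auxin synthesis gene YUC3 at 0.0317 ± 0.0538 against 79.2 ± 48.3. DNA methylation and chromatin genes divided too (14 higher and 9 lower of 27, 15 and 9 when adjusted over the list alone, camera adjusted p = 0.347). CMT3 was at 93.7 ± 17.1 against 7.39 ± 5.21 in the suspensor. The DNA demethylase genes ROS1 and DML3 were at 2.89 ± 0.705 and 0.0650 ± 0.111 against 22.3 ± 11.5 and 28.4 ± 19.3. Suspensor and basal lineage regulators were lower in the embryo proper in 8 of 17 cases and higher in 3 (the same when adjusted over the list alone, camera adjusted p = 0.103). Of 25 photosynthesis genes 8 were lower and 0 higher (camera adjusted p = 0.103), and of 9 seed storage and maturation genes 3 were lower and 1 higher (camera adjusted p = 0.530). Gibberellin synthesis genes counted 2 higher and 1 lower of 5 (camera adjusted p = 0.696). Reference genes counted 4 higher and 2 lower of 7 (camera adjusted p = 0.463), with ACT2 at 125 ± 5.90 against 30.7 ± 13.7 and UBQ10 at 166 ± 69.4 against 455 ± 190.3. These 4 lists counted 8, 2, 1 and 2 members lower and 0, 1, 2 and 4 higher when adjusted over the list alone.

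**Figure D2:**
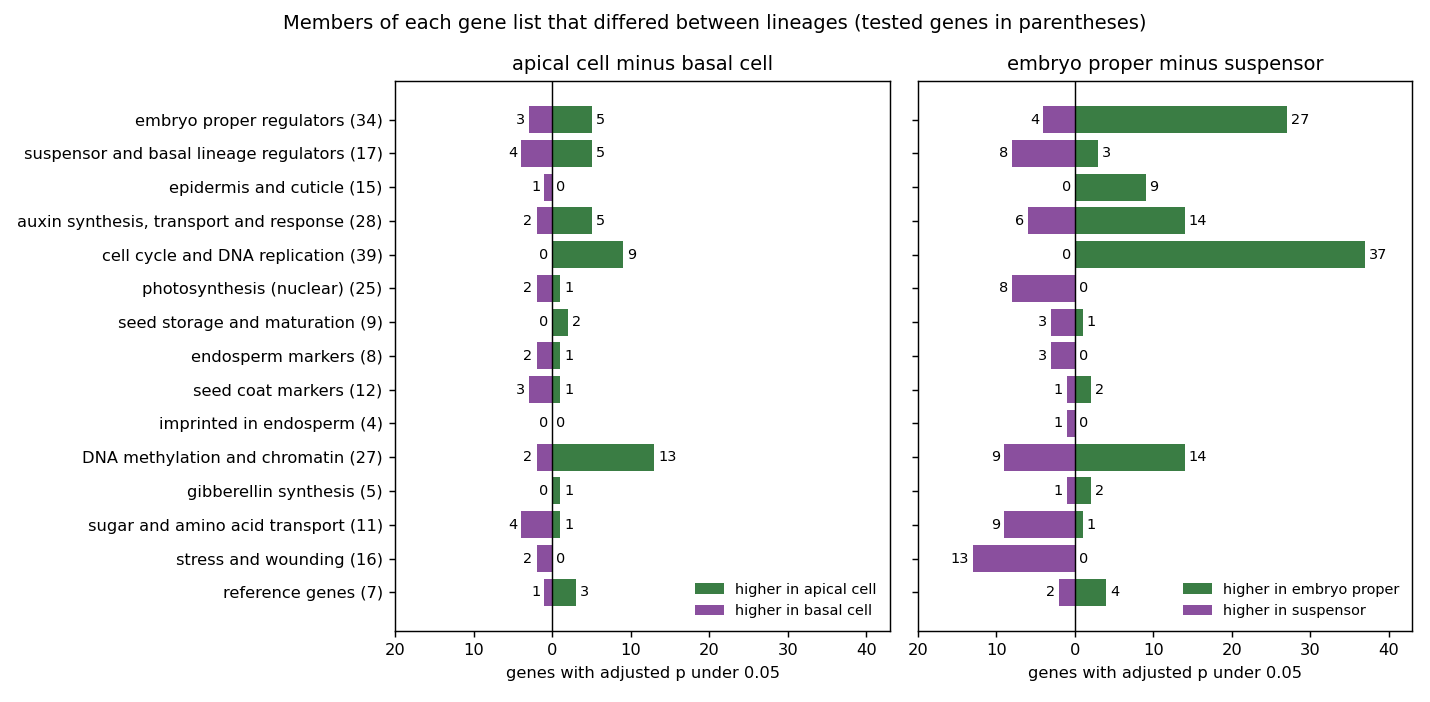
Bars give, for each of the 15 gene lists, the number of tested members called higher (green) or lower (purple) at a limma adjusted p under 0.05, in the apical against the basal cell (left) and in the embryo proper against the suspensor (right). Cell cycle genes count 9 and 0 at the early stage and 37 and 0 at the late stage.

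Of 19 endosperm markers 8 could be tested, and 3 of them were lower in the embryo proper than in the suspensor and 0 higher (the same when adjusted over the list alone, camera adjusted p = 0.103). These were SUC5, which the transporter list also holds, AGL62, at 0.598 ± 0.794 against 11.4 ± 11.4, and ESF1.2, at 3.98 ± 4.57 against 24.9 ± 21.0. The AGL62 call is lost within the cross with a Col mother and the ESF1.2 call within that with a Ler mother (limma adjusted p = 0.164 and 0.304) and, for ESF1.2, with library weights (limma adjusted p = 0.0609). Of 22 seed coat markers 12 could be tested, with 2 higher and 1 lower (the same when adjusted over the list alone, camera adjusted p = 0.696). The flavonoid gene BAN averaged at most 2.65 ± 4.02, in the suspensor, and CHS at most 4.68 ± 10.6, whereas TTG1, which many tissues express, reached 47.2 ± 12.4 in the apical cell. Of 14 genes imprinted in endosperm 4 could be tested, with 0 higher and 1 lower (the same when adjusted over the list alone, camera adjusted p = 0.515), and MEA averaged at most 0.325 ± 0.796.

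Over all genes, limma called 5193 higher and 4072 lower in the embryo proper than in the suspensor, 50.9% of those tested. The median gene was 0.12 higher on the log2 scale in the embryo proper, so the list medians of 3.18 and -2.21 lie well outside the general shift.

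The next comparison followed the apical lineage from the apical cell to the embryo proper. PDF1 rose from 6.60 ± 5.90 to 4614 ± 662 (log2 9.59, SE 0.56, limma adjusted p = 1.23e-11, n = 6 each). The lipid transfer gene LTPG1, which acts in cuticle formation, rose from 0.570 ± 0.827 to 693 ± 273, and the arabinogalactan protein gene AGP9 from 1.91 ± 1.34 to 358 ± 54.1. The copper transporter gene COPT2 fell from 465 ± 133 to 0.110 ± 0.183 (log2 -8.68, SE 0.23) and the ribonuclease gene RNS1 from 531 ± 328 to 1.84 ± 1.40. The annexin gene ANN6 fell from 149 ± 37.2 to 0.0333 ± 0.0641, and the sugar transporter gene SWEET8 from 460.3 ± 149 to 3.43 ± 5.71. Embryo proper regulators rose as a group, with 22 of 34 higher and 2 lower (22 and 3 when adjusted over the list alone, median 2.15, camera adjusted p = 9.67e-14, and adjusted p = 8.8e-05 with an estimated correlation). The auxin response factor ARF5 went from 5.86 ± 2.96 to 131 ± 20.1, and PHB, a class III homeodomain gene, from 1.39 ± 1.36 to 66.2 ± 15.4. Epidermis and cuticle genes rose in 8 of 15 cases and fell in 0 (9 and 0 when adjusted over the list alone, camera adjusted p = 1.47e-07). Auxin genes rose in 10 of 28 and fell in 0 (11 and 1 when adjusted over the list alone, camera adjusted p = 1.12e-04). Both lists were called again (adjusted p = 0.0149 for each with an estimated correlation). Cell cycle genes rose in 2 of 39 cases and fell in 0 (the same when adjusted over the list alone, camera adjusted p = 0.341). In all, 1855 genes rose and 2129 fell, but 2133 and 1996 under quantile normalization and 2235 and 1742 under median-ratio scaling. With only these 12 libraries in the fit, a setting chosen after the data were seen, 6462 were called.

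Along the basal lineage, from basal cell to suspensor, NF-YB6 rose from 1.67 ± 2.60 to 691 ± 240.3 (log2 8.49, SE 0.51, limma adjusted p = 1.18e-11, n = 6 each) and FUS3 from 5.06 ± 4.88 to 244 ± 96.3. The glycine-rich protein gene AT3G24250 rose from 79.1 ± 55.0 to 15723 ± 3414 and TI1 from 0.767 ± 1.82 to 816 ± 516. MLP28, of the major latex protein family, was at 854 ± 308 in the suspensor and listed at 0 in all 6 basal cell libraries. SEN1, a senescence and dark response gene, fell from 121 ± 72.5 to 0.00833 ± 0.0204 (log2 -6.32, SE 0.68), OXS3, an oxidative stress gene, from 113 ± 68.1 to 1.31 ± 2.62, and WOX2 from 94.4 ± 27.1 to 2.77 ± 3.65. Of 39 cell cycle genes 25 fell and 0 rose (the same when adjusted over the list alone, median -2.30, camera adjusted p = 5.45e-05, and adjusted p = 0.242 with an estimated correlation). Among them CDC20-1, an activator of mitotic exit, fell from 435 ± 189 to 29.6 ± 34.5. Stress and wounding genes rose in 12 of 16 cases and fell in 0 (the same when adjusted over the list alone, camera adjusted p = 5.45e-05, and adjusted p = 0.228 with an estimated correlation). Auxin genes rose in 11 of 28 and fell in 4 (the same when adjusted over the list alone, camera adjusted p = 0.0307, and adjusted p = 0.228 with an estimated correlation). WOX9, at 342 ± 84.0 and 229 ± 87.6, was not called (limma adjusted p = 0.153). In all, 3436 genes rose and 4737 fell, and 5891 of these 8173 calls were kept with only the 12 libraries of these cell types in the fit.

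Whether the lineage difference itself changed with stage was tested as an interaction. AT5G66800, of the membrane-associated kinase regulator family, moved from a basal to an apical bias. It was at 2.62 ± 4.43 in the apical and 119 ± 22.4 in the basal cell, then at 73.1 ± 25.3 in the embryo proper and 5.82 ± 6.21 in the suspensor (interaction log2 9.50, SE 0.73, limma adjusted p = 1.16e-09). COPT2 moved the other way (interaction -9.89), from an apical excess over 145 ± 102 in the basal cell to near absence in the embryo proper against 308 ± 144 in the suspensor. The papain-type protease gene CEP1, which acts in developmental cell death, was at 19.3 ± 4.90, 12.2 ± 4.15, 0.542 ± 0.248 and 578 ± 209.7 in apical cell, basal cell, embryo proper and suspensor (interaction -9.12). DRN kept its apical bias, at 39.6 ± 13.2 in the embryo proper and 0.613 ± 1.5 in the suspensor (interaction 0.64, limma adjusted p = 0.455). By list, embryo proper regulators gained in the apical lineage relative to the basal lineage, with 23 higher and 5 lower of 34. Adjusted over the list alone the counts were 25 and 5 (camera adjusted p = 9.06e-06, and adjusted p = 0.012 with an estimated correlation). Cell cycle genes did too, with 24 higher and 0 lower of 39. Adjusted over the list alone the counts were 25 and 0 (camera adjusted p = 9.06e-06, and adjusted p = 0.169 with an estimated correlation). Their median log2 change was -2.30 from basal cell to suspensor but 0.13 from apical cell to embryo proper. Stress and wounding genes lost in the apical relative to the basal lineage in 12 of 16 cases (camera adjusted p = 7.39e-05, and adjusted p = 0.154 with an estimated correlation). Their median log2 change was 1.91 from basal cell to suspensor and -0.37 from apical cell to embryo proper. Sugar and amino acid transporters lost in the same relative sense in 5 of 11 cases and gained in 0 (camera adjusted p = 0.0082, and adjusted p = 0.0452 with an estimated correlation). From apical cell to embryo proper 2 of these transporters rose and 5 fell, and from basal cell to suspensor 5 rose and 1 fell. Epidermis and cuticle genes gained in the apical relative to the basal lineage in 9 of 15 cases and lost in 0 (camera adjusted p = 0.0264, and adjusted p = 0.301 with an estimated correlation). For these 3 lists the counts were the same when adjusted over the list alone. In all 3506 genes had a positive and 2949 a negative interaction. Across genes, which are not independent replicates, the log2 lineage differences at the 2 stages correlated with r = 0.313 and rho = 0.268. Of the genes called, 1014 were higher in the apical lineage and 1071 in the basal lineage at both stages. Independent lists of these lengths would share 611.8 and 496.3. From the apical to the suspensor side and from the basal to the embryo proper side 309 and 282 genes moved, where independent lists would give 479.8 and 632.9.

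Reciprocal crosses ask whether the direction of the cross, and so the mother, alters RNA levels in a given cell type. The files give total RNA per gene, so the shares of maternal and paternal alleles were not analysed here. In the apical cell the annexin gene ANNAT1 was at 172 ± 72.2 with a Ler mother and 0.107 ± 0.185 with a Col mother (log2 -7.22, SE 0.82, limma adjusted p = 4.59e-05, n = 3 each). The phosphatase gene PS2 was at 321 ± 57.0 against 3.49 ± 4.68 and PEPC1, a phosphatase induced by phosphate starvation, at 705 ± 154 against 21.4 ± 18.6. Higher with a Col mother were BT5, a BTB and TAZ domain gene, at 95.7 ± 35.3 against 10.5 ± 2.90, and the zinc finger gene ZF2, at 15.1 ± 6.16 against 1.39 ± 0.904. So was the jasmonate regulator MYC2, at 14.6 ± 5.56 against 0.860 ± 0.512, a call lost without Col replicate 1, Ler replicate 1 or Ler replicate 3 (limma adjusted p = 0.082, 0.0665 and 0.0716). A pseudocount of 0.1 ended the calls of MYC2 and PEPC1. In all 18 genes were higher and 60 lower with a Col mother, 32 and 52 under median-ratio scaling and 32 and 60 under quantile normalization. By list, camera at the preset correlation placed stress and wounding genes and epidermis genes higher with a Col mother (camera adjusted p = 0.001 and 0.0258). Neither was called with an estimated correlation (adjusted p = 0.396 and 0.427) or by fry of limma (adjusted p = 0.414 and 0.462). Of their 16 and 15 members 0 and 0 were called over all genes, and 0 and 1, higher, when adjusted over the list alone. With only the 6 apical libraries in the fit 17 genes were called, 5 of them among the 78. PS2, PEPC1, MYC2, BT5 and ZF2 were no longer called there and ANNAT1 was. Without Ler replicate 1 the count fell to 38.

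**Figure D3:**
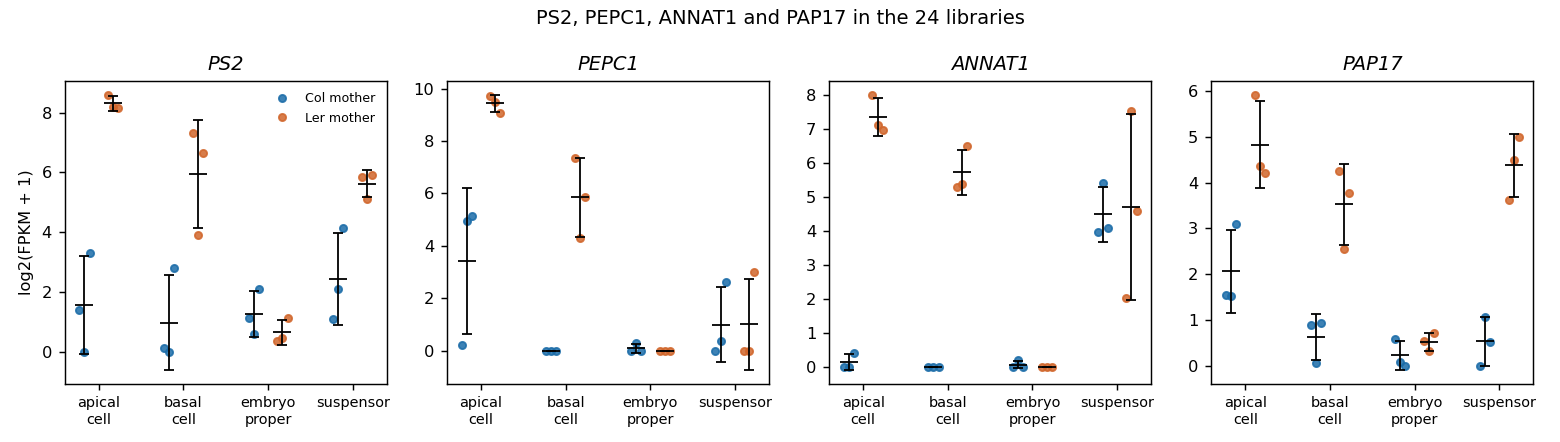
Each point is 1 library, placed by its log2(FPKM + 1), for PS2, PEPC1, ANNAT1 and PAP17 in the 4 cell types (blue Col mother, orange Ler mother, black bars mean and SD, n = 3). In the apical cell all 3 Ler-mother libraries of each gene lie above all 3 Col-mother libraries, and in the embryo proper all 4 genes are near 0.

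In the basal cell the glutathione transferase gene GSTU9 was at 181 ± 111 and AT3G45730, of unknown function, at 191 ± 113 with a Col mother, and both were listed at 0 in the 3 libraries with a Ler mother (limma adjusted p = 0.000565 and 9.41e-07). With a Ler mother ANNAT1 was at 55.7 ± 28.8 and PEPC1 at 79.9 ± 74.8, and both were listed at 0 in the 3 libraries with a Col mother. PS2 was at 90.6 ± 72.8 against 2.02 ± 3.43 (log2 -4.98, limma adjusted p = 0.0018). In all 722 genes were higher and 564 lower with a Col mother, but 624 and 697 under quantile normalization, and no list was called by camera. Library weights raised the count to 5044, with 1261 of the 1286 kept. With the 6 basal libraries alone 319 genes were called, 243 of them among the 1286. Leaving out Ler replicate 2, Col replicate 2 or Col replicate 1 left 569, 757 or 802. Of the 6 libraries 3 have the second protocol wording, which leaves 1 Ler and 2 Col libraries without it. In that subset 858 genes were called, 414 of them among the 1286, but the Ler side is then 1 library, taken to vary as the other groups do, so these counts say nothing about the protocol.

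In the embryo proper limma called 0 genes between the crosses, with 94 at an unadjusted p under 0.05 and 1 called when the 6 embryo proper libraries were fitted alone. WOX2 was at 84.9 ± 14.4 with a Col and 91.2 ± 11 with a Ler mother. WOX9 was at 99.7 ± 21.8 with a Col and 111 ± 12.2 with a Ler mother (n = 3 each). In simulated data this fit recovered 47.2% of genes changed by 2 and 99.2% of those changed by 3 on the log2 scale. Photosynthesis genes lay higher with a Col mother by a median of 0.58 (camera adjusted p = 1.83e-10, and adjusted p = 0.0472 with an estimated correlation), although fry of limma did not call them (adjusted p = 0.912). None of the members was called, over all genes or over the list alone, and RBCS1A was at 38.7 ± 27.0 against 6.61 ± 4.77. Library weights gave 174 calls, and leaving out Col replicate 2 or Ler replicate 1 gave 4 or 1.

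In the suspensor AT1G65500, of unknown function, was at 339 ± 164 with a Col mother and 9.53 ± 14.5 with a Ler mother (log2 6.09, SE 0.74, limma adjusted p = 5.26e-05, n = 3 each). The acid phosphatase gene PAP17 was higher with a Ler mother, at 21.3 ± 9.87 against 0.510 ± 0.548, as was AOC3, a jasmonate synthesis gene, at 52.0 ± 19.7 against 6.05 ± 8.07. In all 529 genes were higher and 236 lower with a Col mother, but 292 and 400 on the TPM scale, and with the 6 suspensor libraries fitted alone 0 were called. The shared estimate of the spread lies under that of the suspensor, and simulated libraries with no difference gave 201.8 calls here on average, so this count is not a measure of the cross. Without Ler replicate 1 or Ler replicate 3 the count was 1330 or 1494. Suspensor and basal lineage regulators and chromatin genes lay lower with a Col mother (camera adjusted p = 0.0167 and 0.00194, and adjusted p = 0.0716 for each with an estimated correlation). Over all genes 0 and 1 members were called lower and 0 higher. Adjusted over the list alone, 3 and 7 were lower and 0 and 1 higher.

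Averaged over the 4 cell types, 73 genes were higher and 71 lower with a Col mother, 67 and 101 on the TPM scale and 99 and 64 under median-ratio scaling. PAP17 (log2 -2.45, SE 0.30, limma adjusted p = 0.000193), ANNAT1 (-3.27) and PS2 (-3.57) were lower with a Col mother, and BT5 (1.17) was higher. Camera placed chromatin genes lower with a Col mother (camera adjusted p = 0.00801, and adjusted p = 0.186 with an estimated correlation; fry adjusted p = 0.0135). Of the 27 members 0 were called over all genes and 1, lower, when adjusted over the list alone. Leaving out any 1 embryo proper library gave 64 to 88 calls, and leaving out apical Col replicate 2 or apical Ler replicate 1 gave 94. Without suspensor Ler replicate 1 or 3 there were 306 and 303.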

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

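The tests of splits of the samples and of each explanation below were chosen after the results were seen, except that of the further phosphate starvation genes.

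The difference between the lineages was not the same at both stages: 6455 genes were called in the test of lineage by stage. Among 100 splits of the samples only the real one gave as many, and the highest of the others gave 1248. For apical against basal cell, embryo proper against suspensor, embryo proper against apical cell and suspensor against basal cell, with only the libraries compared and a fit that holds cell type but not the cross, 1 of 100 splits gave as many calls as the real one, which is the real one itself. In those fits the real counts were 3679, 8855, 6343 and 5395 and the highest others 15, 4, 23 and 12. A chance labelling of the libraries is therefore argued against for these 5 results, at 1 of 100 splits each. Splits of libraries cannot tell cell type from a source that replicates share. The labels do not say that replicates came from separate plants.

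The effect of the cross also differed between cell types. An F test over the 4 cell types called 574 genes. The difference between the cross effects was called for 227 genes between apical and basal cell, 47 between embryo proper and suspensor, 11 between embryo proper and apical cell, and 1023 between suspensor and basal cell. The counts of 574, 47 and 1023 take in the suspensor and use a spread shared by all groups, with which simulated libraries without a difference gave 201.8 calls for the suspensor cross, so they do not measure how far the crosses differ. ANNAT1 and PS2 (AT1G73010) are among the 11, with cross effects that differ by 7.29 and 7.38 on the log2 scale (limma adjusted p = 0.0139 and 0.0189). For the mean of the 4 cell types, 1 of 100 splits gave as many calls (144, highest other 57). This argues against a chance labelling of the libraries there, with the same limit for a source that replicates share. Within a cell type 3 libraries against 3 make only 10 splits, too few for a share under 0.05. Splits with as many calls as the real one numbered 1 in the apical cell (17, highest other 9), 1 in the basal cell (319, highest other 5), 2 in the embryo proper (1, highest other 1) and 10 in the suspensor (0, highest other 0).

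The first pattern weighed is the set of phosphate starvation genes that stood higher with a Ler mother in the apical cell, noticed among the called genes: 12 genes, with a median log2 change of -3.23 and 7 called. PEPC1, for example, was at 705 ± 154 with a Ler and 21.4 ± 18.6 with a Col mother, and GDPD1 at 243 ± 55.0 and 15.0 ± 6.07 (n = 3 each). The library protocol is argued against, since all apical libraries have the same wording and so it cannot part the crosses there, where the median is -3.23; these genes were picked for that difference, so its size is no test of the pattern. Of 7 further phosphate genes listed before their values were seen 4 could be tested, and 4 were fitted lower with a Col mother (limma camera p = 1.5e-06, and p = 0.000896 with an estimated correlation), although 1 was called; they include PHT1;4 at 33.2 ± 27.5 against 7.35 ± 6.25 and PHF1 at 88.0 ± 25.6 against 35.6 ± 16.6. A phosphate response that differs with the mother plant, its soil or its genotype may therefore underlie the pattern. RNA from the maternal seed coat stays open. The summed FPKM of 22 seed coat markers was 8.74 higher with a Ler mother (55.2 ± 11.4 against 46.5 ± 11.6), within the spread. That sum lies close to the level of TTG1 alone given above, a gene that many tissues express. It therefore cannot test for seed coat RNA, and the level of the phosphate genes in seed coat was not measured here.

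The second pattern is that crosses gave no calls in the embryo proper and many in basal cell and suspensor. A spread shared by all cell types is argued against as the cause for the basal cell, since its own libraries, fitted alone, gave 319 calls. For embryo proper and suspensor it cannot be told apart from the effect, or lack of effect, of the cross: the embryo proper gave 1 call with its own libraries but 174 with library weights, and the suspensor, whose replicates vary most, 0 and 14. A shift common to the 4 libraries of the second protocol wording is argued against as the whole cause in the basal cell. With the wording as a covariate 1035 of the 1286 calls were kept. The labels do not say which kit each of the 4 had, and 1 covariate cannot remove effects that differ among them. The library protocol therefore stays open, since the fit without the 4 libraries has 1 Ler basal library and decides nothing. An effect of the parents, such as maternal RNA that persists at the early stage, could explain the basal cell calls and was not tested, since alleles were not analysed here.

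The third pattern is the lower level of cell cycle genes in the suspensor than in the embryo proper. A few genes taking a large share of the FPKM are argued against, since the median log2 difference of the list was 3.21 under median-ratio scaling against 3.18 as deposited. Fewer transcripts seen at a given level are argued against too, since the list lies at percentile 100 of 10000 random lists matched on mean expression, whose central medians ran from -0.37 to 0.74. Slower division in the suspensor could explain the pattern as a hypothesis; division rates were not measured, and camera with an estimated correlation did not call the list.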

How the results depend on the processing

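The fits of only the libraries of the cell types compared, the fits of splits of the samples, the phosphate lists and the gene families were chosen after the data were seen; all other alternatives were fixed before the data were examined.

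The counts of embryo proper against suspensor, suspensor against basal cell and lineage by stage stayed within 1.5 times under the alternative settings named for the fit, at 6437 to 9646, 5879 to 8304 and 5923 to 7189 genes. The fit without the cross used for the splits of the samples gave 5395 for suspensor against basal cell. Library weights gave 6715 calls for apical against basal cell, 6873 for embryo proper against apical cell, and 138, 5044, 174, 14 and 352 for the crosses in apical cell, basal cell, embryo proper, suspensor and on average. Within the Col-mother and the Ler-mother cross, with fewer samples, 2532 and 2668 genes were called for apical against basal cell and 2350 and 2250 for embryo proper against apical cell. Only the libraries compared gave 6462 calls for embryo proper against apical cell and 17, 319, 1 and 0 for the crosses in apical cell, basal cell, embryo proper and suspensor. Without the 4 libraries of the second protocol wording the crosses gave 124 calls in the apical cell, 1477 in the suspensor and 388 on average. No filter gave 12 in the embryo proper, the fit without trend 495 in the suspensor and the 2-fold threshold 95 on average. The cause of these shifts was not tested.

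Leaving out each library in turn gave 38 to 98 calls for the cross in the apical cell (fewest without apical Ler replicate 1), 569 to 1698 in the basal cell (fewest without basal Ler replicate 2), 0 to 4 in the embryo proper (most without Col replicate 2), 556 to 1494 in the suspensor (most without Ler replicate 3), and 64 to 306 on average (fewest without embryo proper Ler replicate 2, most without suspensor Ler replicate 1).

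Deviations of same-numbered libraries correlated from -0.064 to 0.097 between lineages, -0.173 to 0.38 between crosses and -0.081 to 0.2 between stages. Libraries of different number gave -0.107 to 0.107, -0.33 to 0.259 and -0.217 to 0.126. Same-numbered pairs averaged 0.022, 0.012 and 0.036, so the numbers showed no general pairing. Of 12 such pairs each, 0, 1 and 2 exceeded 0.1, the limit set for a pair. The value of 0.38 joins replicate 2 of the embryo proper crosses. A source shared by some same-numbered libraries stays open. With a replicate block 4329 genes were called for apical against basal cell and 9252 for embryo proper against suspensor, and 3667 and 8800 with cross and number as the block.

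Among named genes the log2 change kept its direction and side of the threshold in 7315 cases other than leaving out libraries, lost the call in 329, gained it in 22 and reversed in 3. KCS10 between crosses in the basal cell went to -2.52 without the 4 libraries, a fit with 1 Ler basal library that decides nothing. GAPC1 between apical and basal cell went to 0.006 within the Ler-mother cross, so hardly any difference was left there. EF1A in lineage by stage went to -0.66 under quantile normalization. The cause of the GAPC1 and EF1A shifts was not tested. Of the list tests 1711 stayed, 26 lost the call and 53 gained it. Counts of detected loci moved in 8 cases with the FPKM minimum. Depth limits calls of weak genes, and the log2 scale with a pseudocount shrinks them.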

Other observations

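The 5 gene families below, taken by the words of their products, were chosen after the data were seen, and their tests with them. The words take in relatives too, such as the elongation factor family gene LOS1 in the ribosomal set. Ribosomal protein genes followed the lineages at the late stage. Of 293 tested, 250 were higher in the embryo proper than in the suspensor and 5 lower, with a median log2 difference of 1.78 (limma camera p = 3.66e-42, and p = 0.00127 with an estimated correlation). From basal cell to suspensor 4 rose and 251 fell (median -1.47, p = 4.09e-46 with limma camera, and p = 0.000854 with an estimated correlation), and from apical cell to embryo proper 110 rose and 13 fell (limma camera p = 1.31e-11, but p = 0.0706 with an estimated correlation). Between apical and basal cell 21 were higher and 51 lower, with a median of -0.11 that turned to 0.03 on the TPM scale. AT5G09500, of the ribosomal protein S19 family, was at 517 ± 153 in the apical cell, 448 ± 154 in the basal cell, 5.91 ± 6.14 in the embryo proper and 2.97 ± 3.64 in the suspensor (n = 6 each).

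TRAF-like and MATH-domain genes, whose products often serve as adaptors of ubiquitin ligases, were called in part. Of 51 tested, 12 were higher in the apical than in the basal cell, 0 lower and 39 not called (limma camera p = 8.24e-05, and p = 0.00167 with an estimated correlation), and 1 rose, 21 fell and 29 were not called from apical cell to embryo proper (limma camera p = 2.31e-08, and p = 6.49e-05 with an estimated correlation). From basal cell to suspensor 5 rose and 20 fell (limma camera p = 0.0149, and p = 0.0331 with an estimated correlation). Between embryo proper and suspensor 16 were higher and 11 lower (limma camera p = 0.55, and p = 0.575 with an estimated correlation). AT2G01790 was at 495 ± 92.9 in the apical cell, 37.6 ± 14.6 in the basal cell, 16.5 ± 8.87 in the embryo proper and 0.768 ± 1.80 in the suspensor. F-box genes fell from apical cell to embryo proper as well, with 8 of 243 higher, 60 lower and 175 not called (limma camera p = 5.06e-06, and p = 7.8e-05 with an estimated correlation), and from basal cell to suspensor 22 rose and 81 fell (limma camera p = 0.0509, and p = 0.0389 with an estimated correlation). Between apical and basal cell 31 F-box genes were higher and 19 lower (limma camera p = 0.144, and p = 0.111 with an estimated correlation), and between embryo proper and suspensor 41 and 31 (limma camera p = 0.753, and p = 0.721 with an estimated correlation).

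Of 113 genes for defensin-like, thionin, S1 and other small secreted cysteine-rich or related peptides, with kinases and membrane proteins left out, 0 were higher in the apical than in the basal cell and 44 lower (limma camera p = 6.15e-11, and p = 0.0675 with an estimated correlation). In the embryo proper 9 were higher than in the suspensor and 24 lower (limma camera p = 0.0138, and p = 0.471 with an estimated correlation). From apical cell to embryo proper 39 rose and 4 fell (limma camera p = 2.47e-08, and p = 0.114 with an estimated correlation). From basal cell to suspensor 33 rose and 17 fell (limma camera p = 0.0036, and p = 0.396 with an estimated correlation). LCR48 was at 125 ± 80.3 in the basal cell and 21614 ± 11788 in the suspensor. Invertase and pectin methylesterase inhibitor genes counted 0 higher and 10 lower of 48 in the apical cell (limma camera p = 0.0807) and 2 higher and 14 lower in the embryo proper (limma camera p = 0.000318, and p = 0.139 with an estimated correlation).

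Of the 12 phosphate starvation genes 10 were fitted lower and 2 higher with a Col mother in the basal cell, with 4 called, all 4 lower (limma camera p = 4.78e-05, and p = 0.0345 with an estimated correlation), while in the embryo proper 4 were fitted lower and 3 higher (limma camera p = 0.54, 0 called over all genes). In the suspensor 7 were fitted lower and 3 higher, and 2 were called lower (limma camera p = 0.00214, and p = 0.1 with an estimated correlation). The 12 genes were picked after the values were seen, so these p-values are no test of the pattern. Of the 4 further phosphate genes tested, listed before their values were seen, 3 were fitted lower and 1 higher in the basal cell, with 1 called higher and 0 lower (median log2 change -0.17, limma camera p = 0.939, and p = 0.949 with an estimated correlation).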
